A study of Rattus norvegicus with 28 samples.

How the data were processed

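Lung tissue of Sprague Dawley rats was sampled in 28 libraries from 8 groups, given by injury (none, acute, chronic) and ventilation (none, constant or variable tidal volume). Per the labels, poly(A) RNA was selected with oligo(dT) beads, and strand-specific libraries made by the dUTP method were pooled and sequenced on a HiSeq 2000. The submitters list CASAVA 1.8.0, BWA, bedtools 2.11 and DESeq 1.8.3 with genome build rn4, without the role or order of each, and the file header gives Ensembl version 67 for the genes. How strands and ambiguous reads were counted is not stated in the labels.

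The table analysed is a signal per gene and library as deposited, read counts divided by 1 size factor per library. This unit was checked on the values: in each library at least 99.994% of the values were whole multiples of a single step within 0.1 read. Dividing by the step recovers whole reads, which gave 6024093 to 31923838 reads per library. Deposited totals were far more even, as scaling makes them. No pair of replicates held the same counts, the smallest chi-square per gene between replicates being 18.08. All value columns were used. Of 17002 genes, 489 carry no name and 2786 carry the name of a protein entry in place of a symbol, so 3275 were not named in the text. A table of RefSeq symbols matched 0 of the Ensembl identifiers and served only for synonyms of list members. Labels borne by more than 1 gene (103) were told apart by identifier, and no coordinates are given.

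Genes with a mean deposited value of at least 10 over the 28 libraries were tested (14908). Values were taken as log2(deposited value + 1) and fitted with limma 3.58.1 in R 4.3.3, with a mean for each of the 8 groups, an intensity trend and a robust variance prior. The 14 comparisons were 11 contrasts of groups and 3 differences between contrasts. Tests were two-sided moderated limma tests, with Benjamini-Hochberg adjustment over all genes within a comparison and a threshold of 0.05. No paired analysis was possible because the groups share no replicate numbers. Comparisons, tests, gene lists, named genes and most alternatives were chosen before the data were examined.

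The 31 gene lists for cell types and pathways were tested with camera at a preset correlation of 0.01, adjusted over the 31 lists of each comparison, which makes 434 tests. Of 116 list calls, 0 held when camera estimated the correlation of each list, the smallest adjusted p being 0.21. The camera test compares a list with all other genes, and the count of members past the threshold is given over all genes and adjusted over the list alone. Lists were written from general knowledge, not from these libraries.

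Named genes followed a rule. In each contrast of groups they were the 6 highest and 6 lowest log2 changes among genes past the threshold whose groups did not overlap, with a mean of at least 50 in the higher group and a symbol. For the contrast over all arms the sign had to be the same in each arm. For differences between contrasts they were 3 and 3 without the overlap condition. Up to 4 members past the threshold were added from each list, called or not, and in the called direction where a list was called. Also added were 20 fixed genes, of which 18 were found and 2 (Hspa1b and Spp1) were not found under those symbols. Of these, the text gives the ones described, and 1 fixed gene is not reported here. Differences in shared calls were set against the product of both counts over 14908 genes, with no p because genes are not independent.

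Alternatives were a pseudocount of 10, no filter on low values, quantile normalization, fits limited to the groups compared, leaving out each library, and the number series of the titles as a covariate where it can be estimated. Added after seeing the data were edgeR 4.0.16 quasi-likelihood tests on recovered reads, fits limited to a number series, the covariate for acute injury under variable ventilation, fits without the 2 control_chronic libraries of lowest depth, and list tests leaving out each library. The fit against a single healthy_VCV library assumes that it varies like the other groups.

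The procedure was tested on simulated reads with the depth of each library and the dispersion of each gene, in which 100 genes were changed 2-fold and 100 were changed 4-fold. Recovery at 4-fold was 81% to 95% for contrasts of groups and 68% to 71% for differences between contrasts, and at 2-fold it was 41% to 84% and 20% to 30%. Between 2 and 10 of 14688 unchanged genes were called, and 0 changed genes were called with the wrong sign. Each gene was drawn on its own, with no series effect and no variation shared across genes. These rates therefore check the procedure and need not hold for the real libraries. Splits of the libraries into other groups of the same size were fitted in the same way, all of them or 100 drawn at random. Tables and plots used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.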

Results

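Polyadenylated RNA of the right upper lung lobe of Sprague Dawley rats was sequenced in 28 libraries that fall into 8 groups. Unventilated lungs were uninjured (control_blank, n = 3) or taken 14 days after the induction of chronic injury (control_chronic, n = 5). Ventilated lungs were uninjured, acutely injured or chronically injured, and ventilation kept a constant tidal volume (VCV, volume-controlled) or varied it from breath to breath (noisy). The ventilated groups were healthy_VCV (n = 4), healthy_noisy (n = 3), acute_VCV (n = 3), acute_noisy (n = 4), chronic_VCV (n = 3) and chronic_noisy (n = 3). Depth, as whole reads recovered from the deposited values, ran from 6024093 reads in control_chronic_113 to 31923838 reads in acute_VCV_040. By group it spanned 22277745 to 30960809 reads in control_blank, 6024093 to 17162741 in control_chronic, 17855648 to 21510253 in healthy_VCV and 13002088 to 16255716 in healthy_noisy. The injured ventilated groups spanned 28800053 to 31923838 reads in acute_VCV, 14133931 to 22967405 in acute_noisy, 11280590 to 16842768 in chronic_VCV and 18287629 to 21606891 in chronic_noisy. Genes are given by symbol, with the Ensembl identifier for the leading ones. Their changes are log2 differences ± SE from limma over 14908 genes, and levels are deposited values as mean ± SD.

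Library numbers in the titles begin with 12, 14, 15 or 18, called number series here, and the labels do not say what a series stands for. Series 12 held all control_blank and acute_VCV libraries, and series 18 held all control_chronic libraries. Series 14 held 3 of the 4 healthy_VCV libraries, 2 of the 4 acute_noisy libraries and all chronic_noisy libraries. Series 15 held the remaining healthy_VCV and acute_noisy libraries with all healthy_noisy and chronic_VCV libraries. Within the 2 groups that hold both, 171 genes differed between series 15 and 14, of which 90 were higher and 81 lower in series 15. Taken alone, acute_noisy (2 against 2 libraries) gave 3179 genes, and healthy_VCV (1 against 3) gave 0 by limma, with 119 at an unadjusted p under 0.05. Medians of several lists had opposite signs in these groups, with cytokines and chemokines at -1.74 in acute_noisy and 0.32 in healthy_VCV, interferon response genes at -1.53 and 0.07 and neutrophil genes at -0.93 and 0.24. Cardiac muscle genes were lower in series 15 in both, at -3.87 and -2.18. The first 3 principal components carried 35.8%, 21.5% and 9.4% of the variance. Quantile normalization moved the median change of all genes from -0.03 to -0.13 for constant ventilation in uninjured lungs, and from -0.08 to -0.15 for the difference in mode effect between acute and uninjured lungs.

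**Figure D1:**
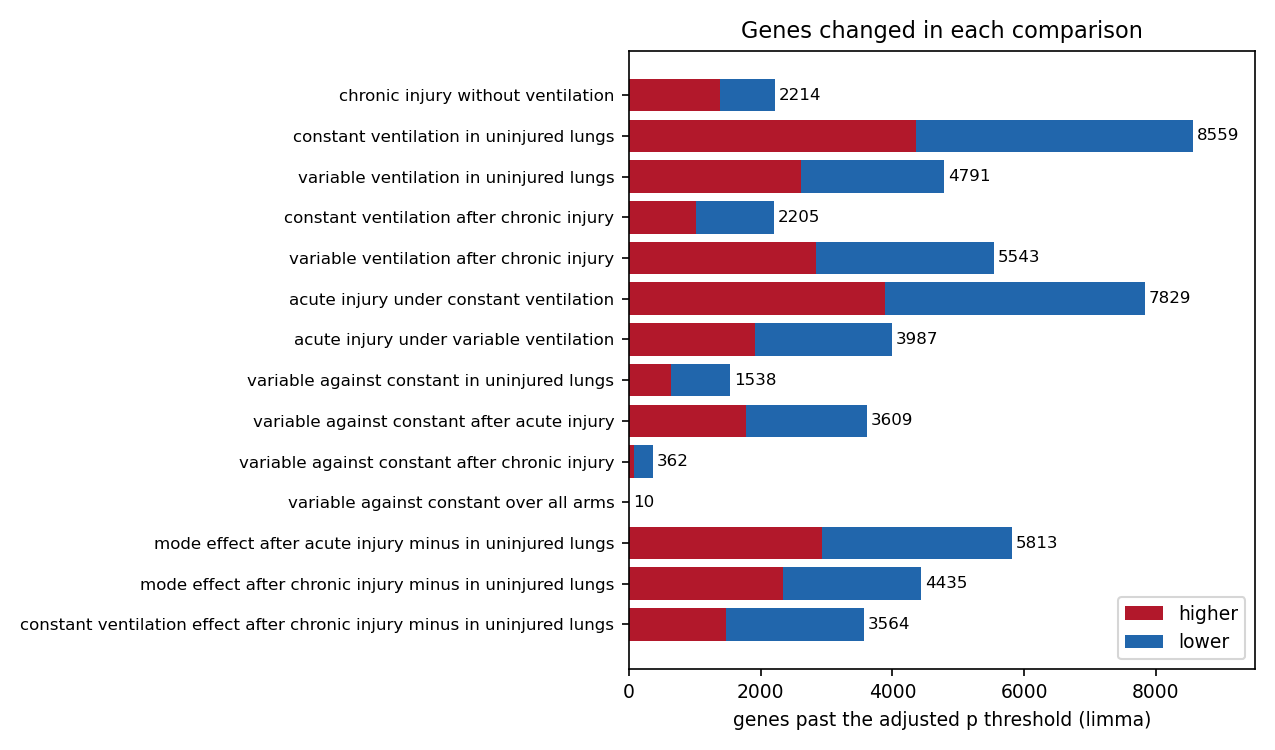
Genes past the adjusted p threshold of limma in each of the 14 comparisons (x axis, number of genes, with higher and lower genes stacked in a bar per comparison on the y axis). The count was highest for constant ventilation in uninjured lungs (8559) and lowest for variable against constant ventilation over all arms (10).

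Chronic injury without ventilation was read from control_chronic against control_blank. By camera the endothelial list was called higher, and the lists of proliferation, of smooth muscle and pericytes, and of cardiac muscle were called lower. Cdh5 (ENSRNOG00000013324), the adhesion protein of endothelial junctions, rose by 1.98 ± 0.48 (adjusted p = 0.012) from 2706 ± 2170 (SD, n = 3) to 7738 ± 1560 (SD, n = 5), and the endothelial transcription factor Erg rose by 1.35 ± 0.24. Nusap1, a mitotic spindle protein, fell by 1.95 ± 0.28 (adjusted p = 0.00056) and Tpx2, which builds the spindle, fell by 1.53 ± 0.32. Des, the intermediate filament protein of muscle, fell by 1.76 ± 0.19 (adjusted p = 3.8e-05). Of 20 endothelial genes 7 were higher and 0 lower (8 higher when adjusted over the list alone, camera adjusted p = 0.00577), but without control_blank_016 the mean difference went from 0.59 to 0.25 and the list was not called (adjusted p = 0.147), and Cdh5 was at 1.07 (adjusted p = 0.203). Of 24 proliferation genes 11 were lower and 0 higher (17 adjusted over the list alone, camera adjusted p = 7.59e-09). The 11 smooth muscle and pericyte genes had 5 lower and 1 higher by either adjustment (camera adjusted p = 0.00579, and 0.137 without control_blank_074). Heart muscle genes, which in rats are also transcribed in the wall of the pulmonary veins, had 12 of 13 lower (13 adjusted over the list alone, camera adjusted p = 3.19e-12), with Tnnt2 at 96.7 ± 18.2 (SD, n = 5) against 1328 ± 427 (SD, n = 3). Small non-coding RNAs led the increases, with RNase_MRP higher by 5.52 ± 0.89 and 1 of 4 genes labelled 7SK (ENSRNOG00000034593) by 4.16 ± 0.76, while the other 7SK genes were at 0.18, 0.66 and -0.51 (adjusted p = 0.8, 0.15 and 0.53). RNase_MRP and the first 7SK gene spread widely within control_chronic, where RNase_MRP averaged 1554 ± 1670 (SD, n = 5).

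In all, 2214 genes passed the test for chronic injury without ventilation (1386 higher, 828 lower). On recovered reads edgeR called 1861 genes with the balance turned, 713 higher and 1148 lower, so the share of higher genes was 38.3% against 62.6%. The 6 list calls, which also covered ribosomal proteins and heat shock proteins, had adjusted p = 0.481 (cardiac muscle, proliferation) or adjusted p = 0.611 with an estimated correlation. Series and group coincide here (12 against 18), so they cannot be told apart. The count was 866 when only these libraries were fitted and 701 without control_chronic_113 and control_chronic_114, the 2 of lowest depth. Leaving out 1 library gave 204 genes without control_blank 016, 1182 without 021, 3635 without 074, 1470 without control_chronic_113 and 1136 without control_chronic_117.

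Constant ventilation in uninjured lungs was read from healthy_VCV against control_blank. By camera, lists of neutrophils, macrophages, the extracellular matrix and glucocorticoid response were called higher, and ciliated cell, heat shock and ribosomal protein lists lower. The club cell and alveolar type 1 lists were not called. The mean log2 of the latter was 13 ± 0.08 (SD, n = 4) in healthy_VCV against 12.76 ± 0.26 (SD, n = 3) in control_blank. Prok2 (ENSRNOG00000010898), a secreted peptide that attracts and is made by myeloid cells, rose by 5.72 ± 0.53 (adjusted p = 2.8e-07), from 3.80 ± 2.48 (SD, n = 3) to 240.5 ± 79 (SD, n = 4). Mmp8 (ENSRNOG00000009907), the neutrophil collagenase, rose by 5.11 ± 0.54, and Il1r2, the decoy receptor of interleukin 1, by 4.74 ± 0.54. Il1b itself rose by 2.25 ± 0.53 (adjusted p = 0.0011), whereas Il6 differed by 0.12 ± 1.19 (adjusted p = 0.94). Scgb1a1, the main secretory protein of club cells, fell by 2.06 ± 0.36, Aqp5, a water channel of alveolar type 1 cells, fell by 1.45 ± 0.34, and Ctgf fell by 1.51 ± 0.23. Among 20 neutrophil genes 13 were higher and 1 lower (14 and 1 adjusted over the list alone, camera adjusted p = 0.00069). The 13 glucocorticoid targets had 8 higher and 0 lower by either adjustment (camera adjusted p = 0.029), with Klf9 higher by 2.16 ± 0.27 and Zbtb16 by 3.71 ± 0.59. Extracellular matrix genes had 15 of 29 higher and 3 lower (16 and 3 adjusted over the list alone, camera adjusted p = 0.0366). Ciliated cell genes had 10 of 14 lower and 2 higher by either adjustment (camera adjusted p = 0.0366), among them Dynlrb2, an axonemal motor subunit, which fell by 2.13 ± 0.37. The 19 macrophage genes had 10 higher and 1 lower by either adjustment (camera adjusted p = 0.0404), and Mertk, a receptor for the uptake of dying cells, was 4.31-fold higher. Ribosomal protein genes had 49 of 63 lower and 2 higher by either adjustment (camera adjusted p = 2.24e-11), with a median of -0.82. Leaving out 1 library ended the calls of 5 of these 7 lists. Heat shock proteins, with 9 of 15 lower by either adjustment (camera adjusted p = 0.0366), were not called without control_blank_016, control_blank_074 or healthy_VCV_062 (adjusted p = 0.0985, 0.0633 and 0.0715). Extracellular matrix was not called without control_blank_016 (adjusted p = 0.0759) or control_blank_021 (adjusted p = 0.0563), and glucocorticoid targets without control_blank_021 (adjusted p = 0.0865). The ciliated cell list was not called without control_blank_074 (adjusted p = 0.108) or healthy_VCV_062 (adjusted p = 0.0599), nor was the macrophage list without control_blank_021, control_blank_074 or healthy_VCV_062 (adjusted p = 0.0692, 0.0984 and 0.0909).

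The comparison of healthy_VCV with control_blank called 8559 genes (4366 higher, 4193 lower). Each of its 7 list calls had adjusted p = 0.972 with an estimated correlation. No series holds both groups, so series and ventilation cannot be told apart. Between acute_VCV and control_blank, both in series 12, the median ribosomal difference was 0.09, with 3 genes higher and 0 lower.

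Variable ventilation in uninjured lungs was read from healthy_noisy against control_blank, the same unventilated libraries as for constant ventilation, so the results are not independent. Prok2 rose by 5.51 ± 0.56 (adjusted p = 4.6e-06), Mmp8 by 4.60 ± 0.57 and Il1b by 2.86 ± 0.57 (n = 3 in each group). Tnf rose by 1.91 ± 0.50, to 152.3 ± 36.1 (SD, n = 3) from 39.5 ± 6.55 (SD, n = 3). Irg1, the macrophage enzyme that makes itaconate, rose by 4.89 ± 1.22. The club cell secretory protein Scgb3a2 fell by 1.95 ± 0.31, Aqp5 fell by 1.89 ± 0.37, and the B cell receptor for immunoglobulin E, Fcer2, fell by 2.92 ± 0.71. The alveolar type 1 list was not called by camera in this comparison either. Neutrophil genes had 13 of 20 higher and 1 lower by either adjustment, that is also adjusted over the list alone (camera adjusted p = 8.58e-07). Ciliated cell genes had 9 of 14 lower (10 adjusted over the list alone, camera adjusted p = 0.00508), with a mean difference of -0.71 that was -0.46 without healthy_noisy_029. B and plasma cell genes had 9 of 15 lower (10 adjusted over the list alone, camera adjusted p = 0.000174), and T and NK cell genes had 9 of 20 lower (10 adjusted over the list alone, camera adjusted p = 0.0124). The interferon response had 4 of 22 higher (3 adjusted over the list alone, camera adjusted p = 0.022), led by Ifit3 with 3.13 ± 0.55. Without healthy_noisy_078 the mean interferon difference went from 0.85 to 0.36 (adjusted p = 0.452), and the list was also not called without control_blank_016 (adjusted p = 0.0857) or control_blank_074 (adjusted p = 0.092). The T and NK cell list was not called without healthy_noisy_078 (adjusted p = 0.112), control_blank_021 (adjusted p = 0.108) or control_blank_074 (adjusted p = 0.0513). NF-kB feedback genes had 3 of 12 higher (8 adjusted over the list alone, camera adjusted p = 0.00915, and 0.0513 without control_blank_074). Cardiac muscle genes had 13 of 13 lower by either adjustment (camera adjusted p = 2.94e-07), and the muscle oxygen store Mb fell by 6.76 ± 1.63.

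For variable ventilation in uninjured lungs 4791 genes passed (2610 higher, 2181 lower), while edgeR gave 4838 with 2041 higher and 2797 lower, a share of 42.2% against 54.5%. The 13 list calls had adjusted p from 0.63 to 0.801 with an estimated correlation. The groups are series 15 and series 12, which cannot be told apart from ventilation. A fit of these libraries alone gave 2059 genes, and the count was 2666 without control_blank 016 and 2803 without healthy_noisy 029.

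Constant ventilation after chronic injury was read from chronic_VCV (n = 3) against control_chronic (n = 5). S100a8 (ENSRNOG00000011557), a calcium-binding protein abundant in neutrophils, rose by 4.02 ± 0.50 (adjusted p = 3.9e-05), from 243.1 ± 173 (SD) to 3569 ± 1830 (SD). Areg, a ligand of the epidermal growth factor receptor, rose by 2.09 ± 0.61, but it spread from 63.89 to 1087 in chronic_VCV against 34.95 to 85.8 in control_chronic. Without chronic_VCV_067 its change was 1.01 (adjusted p = 0.225), and it did not pass either without chronic_VCV_073 or control_chronic_113. Ctgf rose by 0.82 ± 0.22, and by 0.49 without chronic_VCV_069 (adjusted p = 0.159). Airway secretory genes were lower, with Scgb3a2 reduced from 9026 ± 978 (SD) to 2565 ± 631 (SD) and Plunc, an antimicrobial protein of upper airways, from 3562 ± 2460 (SD) to 11.9 ± 11.4 (SD). The 8 club cell genes had 7 lower and 1 higher by either adjustment, over all genes and adjusted over the list alone (camera adjusted p = 0.000125), and the 14 ciliated cell genes had 10 lower (12 adjusted over the list alone, camera adjusted p = 2.92e-08). Neutrophil genes had 11 of 20 higher and 2 lower (13 and 2 adjusted over the list alone, camera adjusted p = 1.21e-08). The unfolded protein response had 7 of 19 higher by either adjustment (camera adjusted p = 1.56e-05), with Trib3 up by 1.72 ± 0.31. Matrix proteases had 4 of 13 higher and 1 lower (5 and 1 adjusted over the list alone, camera adjusted p = 0.00533), with Mmp9 up by 3.17 ± 0.56. Cholesterol synthesis had 5 of 21 higher and 0 lower (6 and 1 adjusted over the list alone, camera adjusted p = 0.000498). Circadian clock genes had 5 of 14 higher (8 adjusted over the list alone, camera adjusted p = 0.000743), with Per2 up by 1.30 ± 0.29. Erythroid genes had 2 of 9 lower (5 adjusted over the list alone, camera adjusted p = 0.00265, and 0.0528 without chronic_VCV_069), with a mean difference of -0.97 that was -0.58 without chronic_VCV_069 and -1.53 without chronic_VCV_067.

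This comparison of chronically injured lungs called 2205 genes (1027 higher, 1178 lower). Its 20 list calls had adjusted p from 0.210 to 0.508 with an estimated correlation. Series 15 and 18 coincide with the groups and cannot be told apart from them. The count was 1389 without control_chronic_113 and control_chronic_114, 1181 without chronic_VCV 069 and 1402 without chronic_VCV 073. Of the genes called for constant ventilation in uninjured and in chronically injured lungs, 1585 moved the same way against 632 from chance, and 45 moved in opposite ways. No library is shared by these comparisons, and their log2 changes correlated at 0.55 across genes, which are not independent replicates.

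**Figure D2:**
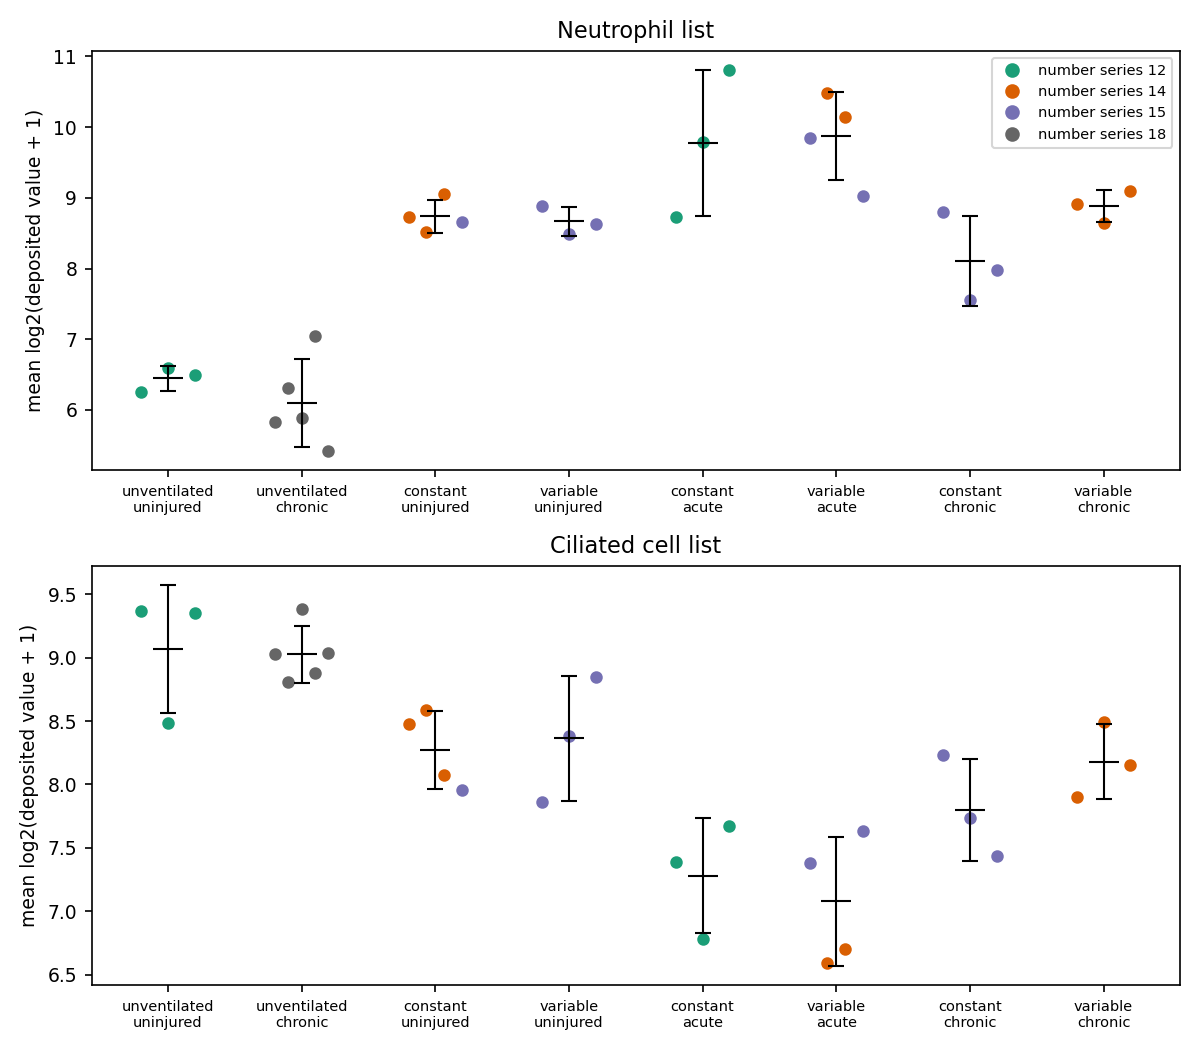
Mean log2(deposited value + 1) of the neutrophil list (upper panel) and the ciliated cell list (lower panel) on the y axis, by group on the x axis, with a point per library coloured by number series and bars for mean ± SD. Neutrophil means were 6.45 and 6.10 in the unventilated groups and 8.11 to 9.87 in the ventilated groups, while ciliated cell means were 9.07 and 9.03 against 7.08 to 8.36.

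Variable ventilation after chronic injury, chronic_noisy (n = 3) against control_chronic (n = 5), shares its unventilated libraries with the comparison for constant ventilation. Fpr1 (ENSRNOG00000011174), a receptor for bacterial peptides on neutrophils, rose by 6.19 ± 0.67 (adjusted p = 2.3e-06), to 101.8 ± 41.9 (SD) from 0.636 ± 1.42 (SD), a level near the floor. Mmp8 rose by 5.43 ± 0.51, S100a8 by 4.75 ± 0.50, and Vcan, a large proteoglycan of the matrix, by 5.28 ± 0.63. Scgb1a1 fell by 1.63 ± 0.35, and Ctrb1, the precursor of a digestive protease known from the pancreas, fell by 5.38 ± 0.70. Neutrophil genes had 14 of 20 higher and 1 lower by either adjustment, which includes the one adjusted over the list alone (camera adjusted p = 6.68e-09). Extracellular matrix genes had 16 of 29 higher and 1 lower (17 and 1 adjusted over the list alone, camera adjusted p = 0.000585), with Fn1, fibronectin, up by 1.83 ± 0.40 and Dcn, decorin, by 2.06 ± 0.42. Cholesterol synthesis had 11 of 21 higher and 1 lower (14 and 1 adjusted over the list alone, camera adjusted p = 0.000373). Ciliated cell genes had 9 of 14 lower by either adjustment (camera adjusted p = 0.00129), and complement, coagulation and acute phase genes had 4 of 17 higher by either adjustment (camera adjusted p = 0.0146). Cardiac muscle genes had 7 of 13 higher by either adjustment (camera adjusted p = 0.00129).

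For variable ventilation after chronic injury 5543 genes passed (2844 higher, 2699 lower), and 2931 without chronic_noisy 084. Its 14 list calls had adjusted p = 0.612 with an estimated correlation. Series 14 and 18 coincide with these groups, so they cannot be told apart. Calls shared with variable ventilation in uninjured lungs numbered 2709 in the same direction against 893 from chance, and 103 in opposite directions, with a correlation of 0.54 across genes and no shared library.

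Acute injury under constant ventilation was read from acute_VCV (n = 3) against healthy_VCV (n = 4). Krt17 (ENSRNOG00000026371), a keratin of basal and injured epithelium, rose by 9.67 ± 0.76 (adjusted p = 8.4e-09), from 11.6 ± 8.91 (SD) to 8185 ± 936 (SD). The cytokine Il24 (ENSRNOG00000004470) rose by 8.52 ± 0.73, to 1262 ± 143 (SD) from 2.56 ± 1.14 (SD), and the serine protease Prss22 by 7.50 ± 0.63. Il6 (ENSRNOG00000010278) rose by 6.90 ± 1.19 (adjusted p = 4.9e-05), Ccl2, which attracts monocytes, by 4.44 ± 1.01, Areg by 3.28 ± 0.64, Ctgf by 2.43 ± 0.23, and Timp1, an inhibitor of matrix proteases, by 4.68 ± 0.51. Hydin, a protein of motile cilia, fell by 3.93 ± 0.55. The 25 cytokines and chemokines had 14 higher and 0 lower by either adjustment, the one adjusted over the list alone included (camera adjusted p = 0.00899). Stretch and YAP target genes, which respond to mechanical tension, had 13 of 20 higher and 4 lower (14 and 5 adjusted over the list alone, camera adjusted p = 0.017). Heat shock proteins had 10 of 15 higher by either adjustment (camera adjusted p = 0.00765), with the mitochondrial chaperone Hspe1 up by 1.95 ± 0.18. Hypoxia and glycolysis genes had 8 of 16 higher by either adjustment (camera adjusted p = 0.024, and 0.0652 without acute_VCV_049), with Ldha up by 1.76 ± 0.19. Alveolar type 1 genes had 9 of 15 lower and 2 higher by either adjustment (camera adjusted p = 0.024), among them the basement membrane chain Col4a3, which fell by 2.16 ± 0.23. Ribosomal protein genes had 53 of 63 higher (56 adjusted over the list alone, camera adjusted p = 6.07e-14), with a median of 0.99. Their median between acute_VCV and control_blank, which share series 12, was 0.09.

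A total of 7829 genes passed for acute injury under constant ventilation (3894 higher, 3935 lower), and its 7 list calls had adjusted p = 0.979 with an estimated correlation. Series 12 is set against series 14 and 15 here, so series and injury cannot be told apart.

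Acute injury under variable ventilation, acute_noisy (n = 4) against healthy_noisy (n = 3), had the same leading genes. Krt17 rose by 9.17 ± 0.76 (adjusted p = 1.5e-07), from 8.39 ± 7.47 (SD) to 3559 ± 1800 (SD), and Il24 by 7.77 ± 0.73. Il6 rose by 6.16 ± 1.19 (adjusted p = 0.0014), Prss22 by 6.04 ± 0.63, Ccl2 by 4.40 ± 1.01, Timp1 by 3.59 ± 0.51, Areg by 3.32 ± 0.64 and Ctgf by 1.32 ± 0.23. Tfpi2, an inhibitor of serine proteases, rose by 5.82 ± 1.04, and Sostdc1, a secreted antagonist of BMP signalling, fell by 3.44 ± 0.62. Cytokines and chemokines had 13 of 25 higher and 1 lower (14 and 1 adjusted over the list alone, camera adjusted p = 1.16e-05). The stretch and YAP target genes had 10 of 20 higher and 0 lower by either adjustment (camera adjusted p = 6.45e-05). Ciliated cell genes had 12 of 14 lower by either adjustment (camera adjusted p = 2.87e-06), with Mlf1 reduced by a log2 change of -1.89 ± 0.33. Heat shock proteins had 9 of 15 higher (10 adjusted over the list alone, camera adjusted p = 0.000204), and the stress-induced chaperone Hspa1a rose by 3.67 ± 0.81. Neutrophil genes had 7 of 20 higher by either adjustment (camera adjusted p = 0.00342).

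Acute injury under variable ventilation changed 3987 genes (1922 higher, 2065 lower). By edgeR 4157 genes passed with 2643 higher, a share of 63.6% against 48.2%. The 14 list calls had adjusted p from 0.544 to 0.712 with an estimated correlation. With series as a covariate 732 genes passed, and 151 passed when acute_noisy was limited to its 2 libraries of series 15, the series of all healthy_noisy libraries. Krt17 was then higher by 8.68 and 8.62, Il24 by 7.48 and 7.46 and Ctgf by 1.34 and 1.32, all past the threshold. Il6, at 4.64 with the covariate, passed only with the covariate. Fitting these 7 libraries alone left 8 genes. Without acute_noisy 047 the count was 1555, without 050 it was 1711, without 053 it was 6146, without healthy_noisy 029 it was 2256, and without 061 there were 874 higher and 766 lower. Both acute comparisons called 1758 genes in the same direction against 1047 from chance and 282 in opposite directions, with a correlation of 0.32 across genes.

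**Figure D3:**
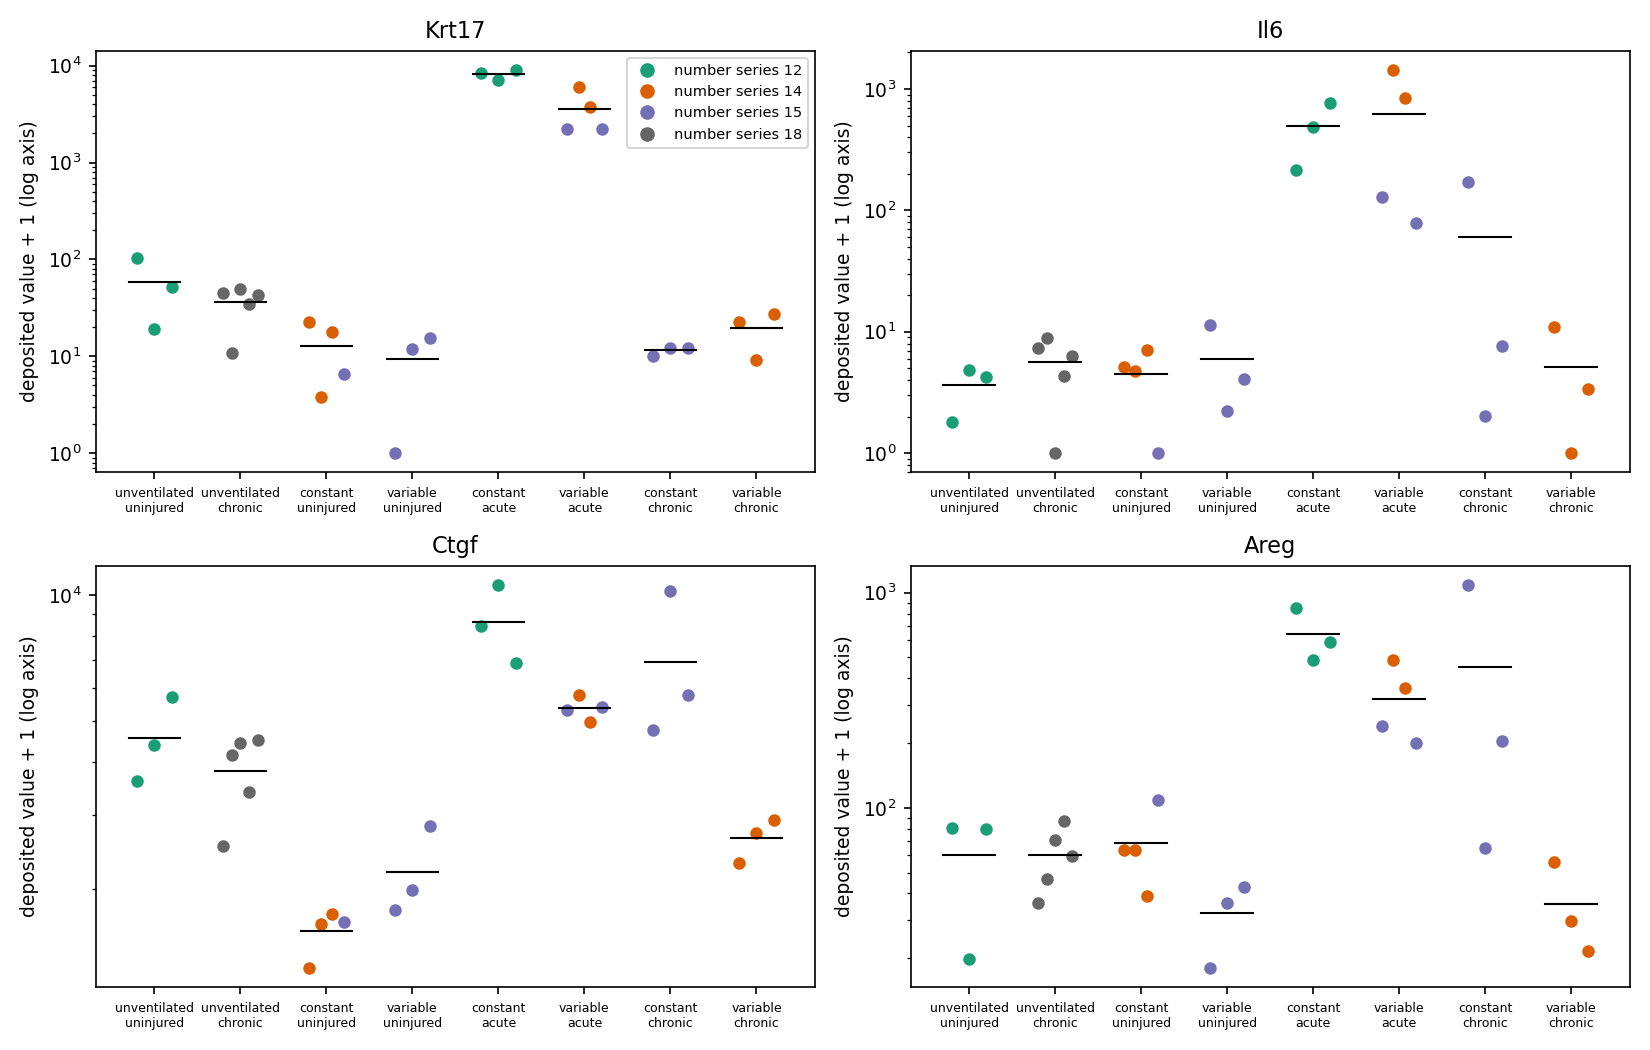
Deposited values + 1 (log y axis) of Krt17, Il6, Ctgf and Areg in the 8 groups (x axis), with a point per library coloured by number series and a line at the arithmetic mean. Krt17 lay between 2220 and 9031 in the 7 acutely injured libraries and between 0 and 102.1 in the other libraries.

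Variable was compared with constant ventilation in uninjured lungs, healthy_noisy (n = 3) against healthy_VCV (n = 4), to ask what breath-to-breath variation adds. The cardiac myosin chain Myh6 fell by 4.93 ± 1.55 (adjusted p = 0.046), from 2325 ± 1260 (SD) to 100.5 ± 94.3 (SD). Fbln2, a basement membrane glycoprotein, fell by 2.01 ± 0.45 (adjusted p = 0.026). Leaving out 1 of the 7 libraries ended the call of Myh6 in 6 cases and that of Fbln2 in 5, with adjusted p up to 0.169 and 0.134, both without healthy_noisy_061. Cardiac muscle genes had 9 of 13 lower (11 adjusted over the list alone, camera adjusted p = 2.21e-06). Extracellular matrix genes had 5 of 29 lower (15 adjusted over the list alone, camera adjusted p = 2.21e-06), and ribosomal protein genes 10 of 63 higher (19 adjusted over the list alone, camera adjusted p = 4.98e-06). Smooth muscle and pericyte genes had 3 of 11 lower (4 adjusted over the list alone, camera adjusted p = 0.0486), and alveolar type 1 genes had 5 of 15 lower by either adjustment (camera adjusted p = 0.04, and 0.0828 after quantile normalization). Neither of these lists was called without healthy_VCV_062 (adjusted p = 0.0818 each) or healthy_noisy_078 (adjusted p = 0.24 for the former, 0.12 for the latter). None of the 18 cytokine, injury and epithelial genes named in advance passed by limma, with Il6 at 0.37 ± 1.19 and Ctgf at 0.45 ± 0.23.

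Between modes in uninjured lungs 1538 genes passed (642 higher, 896 lower), and the 5 list calls had adjusted p = 0.998 with an estimated correlation. With series as a covariate limma called 0 genes, with 1582 at an unadjusted p under 0.05. Against the single healthy_VCV library of series 15 it called 0, with 1770 at an unadjusted p under 0.05, while edgeR without series called 504 higher and 947 lower. The median absolute change of the 1538 genes went from 0.84 to 0.57 with the covariate and their median SE from 0.23 to 0.28. A fit of these groups alone gave 3886 genes. Leaving out healthy_VCV 025, 057, 060 or 062 gave 1, 2, 18 or 477 genes, and leaving out healthy_noisy 029 or 061 gave 4 or 1.

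**Figure D4:**
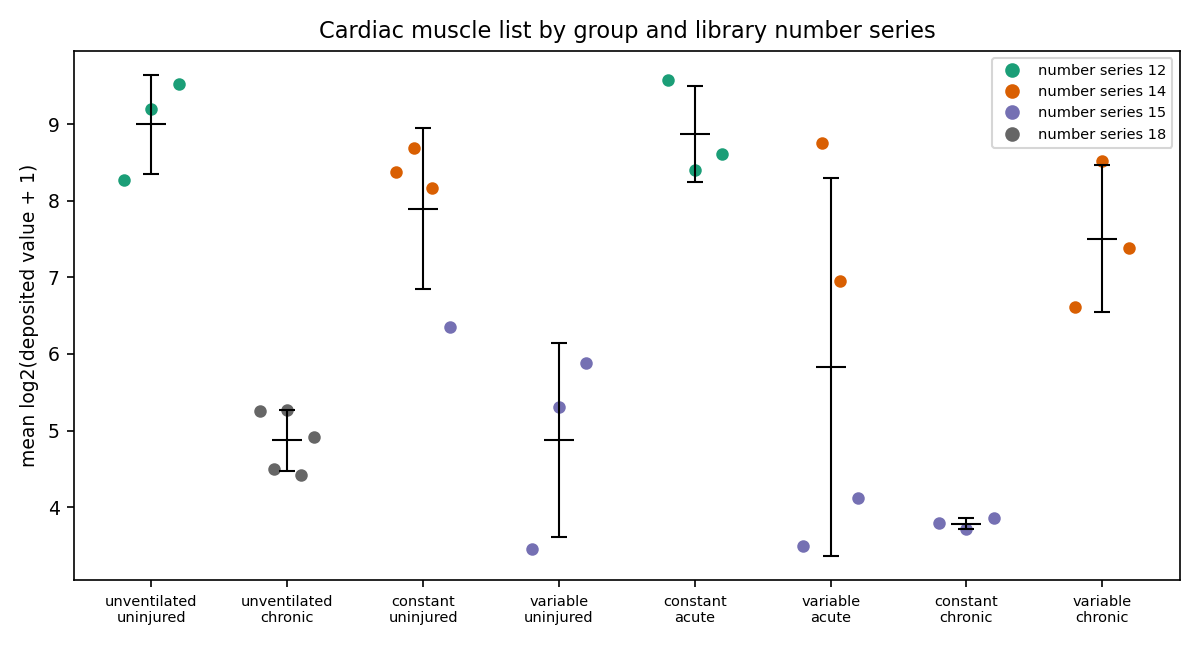
Mean log2(deposited value + 1) of 13 cardiac muscle genes (y axis) by group (x axis), with a point per library coloured by number series and bars for mean ± SD. Within acute_noisy the series 15 libraries lay at 3.49 and 4.11 and the series 14 libraries at 8.76 and 6.95.

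After acute injury, acute_noisy (n = 4) was compared with acute_VCV (n = 3). Ctgf was lower under variable ventilation, where it fell by 0.66 ± 0.23 (adjusted p = 0.039), from 8629 ± 1850 (SD) to 5372 ± 327 (SD). Its call ended without 5 of the 7 libraries, and its change was -0.51 without acute_VCV_045 (adjusted p = 0.162). The other inflammatory genes named in advance did not pass, with Il6 at -0.37 ± 1.19 (adjusted p = 0.85) and Areg at -1.05 ± 0.64. Kcna3, a potassium channel of lymphocytes, rose by 2.45 ± 0.39, and Mb fell by 5.70 ± 1.53 (adjusted p = 0.072 without acute_VCV_040). Ribosomal protein genes had 40 of 63 lower (42 adjusted over the list alone, camera adjusted p = 1.55e-13), and cardiac muscle genes had 12 of 13 lower (13 adjusted over the list alone, camera adjusted p = 4.32e-05). Both lists had adjusted p = 0.98 with an estimated correlation. In all 3609 genes passed (1774 higher, 1835 lower). Series and group cannot be told apart, since acute_VCV is series 12 alone. The count was 2006 with the series 15 libraries of acute_noisy and 5546 with those of series 14, and 780 without acute_VCV 040 or 2206 without acute_noisy 050. In a fit of these 7 libraries alone limma called 0 genes, with 4190 at an unadjusted p under 0.05, while edgeR on all 28 libraries called 3632.

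After chronic injury, chronic_noisy was compared with chronic_VCV (n = 3 in each). A part of the early response genes, 5 of 26, was lower under variable ventilation. Fosl1 (ENSRNOG00000020552), a subunit of the AP-1 transcription factor, fell by 3.54 ± 0.64 (adjusted p = 0.012), from 497.0 ± 653 (SD) to 20.7 ± 9.06 (SD). Jund fell by 3.03 ± 0.59, Egr1 fell by 3.05 ± 0.79, Areg fell by 2.88 ± 0.69 and Ctgf fell by 1.32 ± 0.25 (adjusted p = 0.012). Ctrb1 fell by 4.66 ± 0.79, and the cardiac genes Myl7 and Myh6 rose by 8.05 ± 1.89 and 7.45 ± 1.66. Immediate early genes had 5 of 26 lower (14 adjusted over the list alone, camera adjusted p = 8.22e-10), and without chronic_VCV_067 their mean difference went from -1.25 to -0.54 (adjusted p = 5.96e-05). The stretch and YAP target genes had 3 of 20 lower (6 adjusted over the list alone, camera adjusted p = 0.00767). Cardiac muscle genes had 6 of 13 higher (12 adjusted over the list alone, camera adjusted p = 8.22e-10). Mesothelial genes had 1 of 9 lower by either adjustment (camera adjusted p = 0.00392). This was Krt19, a keratin also found in airway epithelium, which fell by 0.87 ± 0.22. The proliferation list was called higher without each library in turn (camera adjusted p up to 0.00962). Neutrophil, erythroid, and T and NK cell lists were called higher, but not without chronic_VCV_069 (camera adjusted p = 0.268, 0.406 and 0.849). Heat shock protein and ribosomal protein lists were called lower. These calls ended without chronic_VCV_067 and without chronic_noisy_084 (camera adjusted p = 0.573 and 0.0951).

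The chronic arm changed 362 genes between modes (84 higher, 278 lower), and its 10 list calls had adjusted p = 0.809 with an estimated correlation. The groups are series 14 and series 15 throughout, and with the series as a covariate, estimated from the other groups, 9 genes passed, Ctrb1 among them at -6.715 (adjusted p = 0.00164). The median absolute change of the 362 genes went from 0.88 to 0.72 with the covariate and their median SE from 0.21 to 0.28. A fit of these 6 libraries gave 33 genes. The count was 8, 702 or 157 without chronic_VCV 067, 069 or 073, and 202, 15 or 14 without chronic_noisy 075, 079 or 084. Within chronic_VCV the early genes varied widely, with Egr1 between 710.0 and 20310. Without chronic_VCV_067 Fosl1 was at -2.34, Jund at -2.49, Egr1 at -1.76 and Areg at -1.80, with adjusted p = 0.0638, 0.116, 0.277 and 0.204. Ctrb1, Myl7 and Myh6 did not pass without it either (adjusted p = 0.0638, 0.123 and 0.123). Ctgf did not pass without chronic_noisy_079 (adjusted p = 0.0519), and Krt19 was at -0.52 without chronic_VCV_073 (adjusted p = 0.126). In uninjured lungs Jund went the other way, higher under variable ventilation by 1.87 ± 0.55 (limma adjusted p = 0.04). Its means were 2540 in healthy_noisy and 3597 in chronic_VCV, both series 15. They were 726.4 in healthy_VCV, mostly series 14, and 405.5 in chronic_noisy, series 14.

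Averaged over the uninjured, acute and chronic arms, 10 genes differed between modes (2 higher, 8 lower under variable ventilation). In each arm the modes differ in number series, and no fit with the series was made here. Mode and series therefore cannot be told apart in this contrast. Acta1 (ENSRNOG00000017786), the actin of skeletal muscle, fell by 1.95 ± 0.25 (adjusted p = 0.00094) and was lower in each arm, with 452.8 ± 237 (SD, n = 4) against 1576 ± 387 (SD, n = 3) after acute injury. It stood at 33.1 ± 6.08 (SD, n = 3) against 221.3 ± 72.4 (SD, n = 3) after chronic injury and 19 ± 7.38 (SD, n = 3) against 45.2 ± 9.08 (SD, n = 4) without injury. F2rl1, a receptor cleaved by trypsin-like proteases, fell by 0.61 ± 0.11, and Gprc5a fell by 0.57 ± 0.11, but leaving out 1 of the 20 libraries ended their calls in 11 and 15 cases. Gprc5a is a member of the alveolar type 1 list, which was not called by camera in this contrast. Immediate early genes had 0 of 26 past the test over all genes by limma and 1 lower adjusted over the list alone (camera adjusted p = 0.000105, and 0.0338 without chronic_VCV_067, where the mean difference went from -0.41 to -0.18), and 1745 of all genes had an unadjusted p under 0.05. The 7 list calls had adjusted p = 0.985 with an estimated correlation. After quantile normalization 1 gene passed, 0 higher and 1 lower, a share of 0% higher against 20%, and 1 passed in a fit of the ventilated groups alone. By edgeR 14 genes passed, and leaving out 1 library gave between 1 and 52 genes, the highest without chronic_VCV 069.

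Whether the effect of mode differed between arms was tested as an interaction. Acute against uninjured lungs gave 5813 genes (2927 higher, 2886 lower), with extracellular matrix genes higher in 16 of 29 and lower in 0 (19 and 0 adjusted over the list alone, camera adjusted p = 0.000197). Ribosomal protein genes were lower in 45 of 63 (46 adjusted over the list alone, camera adjusted p = 1.86e-11), and both lists had adjusted p = 0.99 with an estimated correlation. As acute_VCV is series 12 alone, healthy_noisy series 15 alone and healthy_VCV mostly series 14, this difference and the number series cannot be told apart. Chronic against uninjured lungs gave 4435 genes (2345 higher, 2090 lower), led by 13 of 13 cardiac muscle genes higher by either adjustment, also adjusted over the list alone (camera adjusted p = 2.09e-08). Mesothelial genes, which mark the lung surface, had 4 of 9 lower (5 adjusted over the list alone, camera adjusted p = 0.0118), and these 2 lists had adjusted p = 0.869 with an estimated correlation. With series as a covariate 6 genes passed this interaction, with 1946 at an unadjusted p under 0.05. Their count was 2535 without chronic_VCV 067, 2766 without chronic_noisy 084 and 2797 without healthy_noisy 061.

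The effect of constant ventilation differed between chronically injured and uninjured lungs in 3564 genes (1479 higher, 2085 lower). Endothelial genes had 8 of 20 lower and 1 higher by either adjustment, also adjusted over the list alone (camera adjusted p = 0.0202, but 0.118 without control_blank_016 and 0.0791 without chronic_VCV_069), with Cdh5 at -2.83 ± 0.70 and the receptor subunit Calcrl at -2.60 ± 0.54. Heat shock proteins had 6 of 15 higher (7 adjusted over the list alone, camera adjusted p = 0.000963), and the 3 list calls had adjusted p = 0.916 with an estimated correlation. Ctgf differed by 2.32 ± 0.32 (adjusted p = 0.0021). On recovered reads edgeR gave 3438 genes with 1836 higher and 1602 lower, a share of 53.4% against 41.5%. The count was 943 without control_blank 016 and 1150 without chronic_VCV 067, and each of the 4 groups has its own mix of number series, which cannot be told apart from the difference.

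The alveolar type 2 and surfactant, mast cell and eosinophil, and oxidative stress (Nrf2) target lists were called in none of the 14 comparisons by camera on the deposited scaling. The first was past the threshold after quantile normalization in chronic_VCV against control_chronic (adjusted p = 0.006) and in chronic_noisy against control_chronic (adjusted p = 0.0446), where 3 of its 13 genes were higher in each.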

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

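The tests in this part on cardiac genes, the test of an interaction with the number series and the test of an effect of chronic injury on small RNAs with ventilation were chosen after the results were seen; the correlations with the series effect inside acute_noisy and the histone test were chosen before, and the correlations with that inside healthy_VCV after.

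A library lay far from the others of its group in 8 of 156 value and group pairs tested, where chance gives about 1 in 20. Only healthy_VCV, acute_noisy and control_chronic held enough libraries for this test, so libraries of the other groups could not be flagged. On the mean log2 scale, circadian clock genes stood at 9.261 in acute_noisy 053 against 8.996 to 9.015 in the others, and endothelial genes at 11.12 in acute_noisy 046 against 11.48 to 11.51. Interferon response genes stood at 9.081 in healthy_VCV 057 against 9.53 to 9.567. In control_chronic, erythroid genes stood at 9.411 in control_chronic_115 against 10.06 to 10.3, glucocorticoid targets at 10.19 in control_chronic_116 against 9.112 to 9.293, and unfolded protein response genes at 10.39 in control_chronic_117 against 10.11 to 10.18. The deposited value of Cxcl2 was 173.3 in control_chronic_116 against 9.53 to 17.84, and that of Sftpc was 233000 in healthy_VCV 062 against 178700 to 183300.

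The effect of variable against constant ventilation differed between acutely injured and uninjured lungs in an interaction test for 10 named genes. Its groups differ in number series, acute_VCV being series 12 alone, so injury and series cannot be told apart here. The log2 difference was 5.15 ± 1.89 for Retn, 4.47 ± 0.90 for Itga1, 4.10 ± 1.06 for Clstn2 and 1.63 ± 0.63 for Col1a1. It was -3.29 ± 1.04 for Ctrb1, -3.11 ± 0.85 for Ptprh, -3.02 ± 0.74 for C4bpb, -1.61 ± 0.52 for Scgb1a1, -1.11 ± 0.32 for Ctgf and -1.10 ± 0.31 for Sftpc. Adjusted p ran from 0.00097 (Itga1) to 0.043 (Col1a1). Leaving out 1 of the 14 libraries ended the call of Col1a1 in 10 cases, of Retn in 8 and of Scgb1a1 in 1, with adjusted p up to 0.119, 0.0788 and 0.0585, each without healthy_noisy_061.

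Between chronically injured and uninjured lungs the effect of mode differed for 9 named genes. Its groups also differ in number series, so an effect of injury and the series cannot be told apart here. Over all genes, 6 passed this interaction with the series as a covariate, in place of 4435. The difference was 13.30 ± 2.59 for Myl7, 12.37 ± 2.27 for Myh6 and 10.69 ± 2.24 for Mb. For Ctrb1 it was -6.28 ± 1.08, for Slc24a5 and Slc5a2 -5.75 ± 1.02 each, for Egr1 -2.98 ± 1.08, for Tnf -1.85 ± 0.69 and for Ctgf -1.76 ± 0.34. Adjusted p ran from 0.00089 (Ctrb1) to 0.046 (Tnf). Leaving out 1 of the 13 libraries ended the call of Tnf in 10 cases and of Egr1 in 8, and without chronic_VCV_067 they were at -1.46 (adjusted p = 0.148) and -1.69 (adjusted p = 0.171).

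The effect of constant ventilation differed between chronically injured and uninjured lungs by 3.79 ± 0.59 for Acta1, 3.37 ± 1.15 for Ccl7, 2.65 ± 0.55 for Tnfrsf12a and 2.32 ± 0.32 for Ctgf. It differed by -5.43 ± 1.29 for RNase_MRP and -4.02 ± 1.05 for Muc5b. RNase_MRP averaged 1554 ± 1670 (SD, n = 5) in control_chronic and 20.31 ± 11.5 (SD, n = 3) in control_blank. With constant ventilation it averaged 130.7 ± 92.9 (SD, n = 3) in chronic_VCV and 173.7 ± 209 (SD, n = 4) in healthy_VCV. The control_chronic libraries form a number series of their own. Each group compared has its own mix of series, which cannot be told apart from the differences listed here. For Glycam1, which was at 0 in all 3 chronic_VCV libraries, the fitted -5.09 ± 1.85 depends on the pseudocount and is no bound. Adjusted p ran from 0.0021 (Acta1, Ctgf) to 0.048 (Glycam1). Leaving out 1 of the 15 libraries ended the call of Glycam1 in 13 cases and of Ccl7 in 9, with adjusted p up to 0.104 and 0.157, both without chronic_VCV_067.

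Cardiac muscle genes were lower under variable ventilation in uninjured and acutely injured lungs, with list medians of -2.98 and -2.82, and higher after chronic injury, with 3.49. That sign argues against variable ventilation acting in 1 direction as the whole cause. With the series as a covariate the medians were -0.72 (median SE 0.73) in uninjured and 0.28 (median SE 0.85) in chronically injured lungs, so a smaller effect in 1 direction stays open. Inside the 2 groups with both number series, series 15 minus series 14 gave a median of -3.26 over the same 13 genes (-3.87 in acute_noisy, -2.18 in healthy_VCV), which is consistent with a difference in the tissue sampled that follows the series, such as more or less vein wall or heart, as Myh6 at 2325 ± 1260 (SD, n = 4) in healthy_VCV and 6.25 ± 3.59 (SD, n = 3) in chronic_VCV might reflect. Of the 13 genes 0 are in another list, and no sort or gate was applied to the tissue. With the series as a covariate the list median of the difference in mode effect between chronic and uninjured lungs went from 6.69 to 1.18, with a median SE of 1.29 and 1.33, and 11 of the 13 genes were positive. A smaller effect of mode whose direction depends on chronic injury stays open.

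Mode effects across all genes had opposite signs in uninjured and chronically injured lungs, with a correlation of -0.7 across genes between comparisons that share no library, genes not being independent replicates. Series 15 holds all healthy_noisy and all chronic_VCV libraries, so a series effect enters these comparisons with opposite signs. The difference between series 15 and 14 inside acute_noisy correlated at -0.48 with the mode effect after chronic injury and at 0.61 with that in uninjured lungs, which is consistent with a part of both effects following the number series. That difference rests on 2 against 2 acutely injured lungs with 3179 genes, so differences between single animals enter it. Inside healthy_VCV, 1 library against 3, the difference correlated at 0.21 with that inside acute_noisy and at -0.3 with the mode effect after chronic injury, the signs that a series effect predicts. With the series as a covariate 6 genes passed the interaction in place of 4435, because the median absolute change of those 4435 went from 1.17 to 0.66 while the median SE went from 0.32 to 0.48. Of them 4261 had the same sign in both fits. An interaction of mode with chronic injury therefore cannot be told apart from the series, since each chronic group lies in 1 series.

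Small non-coding RNAs were among the genes highest in control_chronic against control_blank, yet the whole class of 74 had a median of -0.42 with 10 higher and 7 lower, so the pattern concerns single members. More RNA without a poly(A) tail in series 18 could also raise histone genes. Their median was 0.49 over 10 genes with 2 higher, and the interquartile range across these genes was 0.64. The median lay between the limits set in advance for and against this explanation, so the test cannot tell. An effect of chronic injury of like size with ventilation would raise the 10 higher members there too. Their median was 3.05 in control_chronic against control_blank. It was 0.76 in chronic_VCV against healthy_VCV (interquartile range 0.67) and -0.70 in chronic_noisy against healthy_noisy (interquartile range 0.64). The 10 members were chosen by their rise in the first comparison, so a smaller median elsewhere is expected from the choice alone. The ventilated comparisons also set series 15 against mostly series 14, or series 14 against series 15. These medians therefore cannot decide on an effect of like size. An effect of chronic injury that is confined to unventilated lungs also stays open. It cannot be told apart from series 18, which holds all control_chronic libraries.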

How the results depend on the processing

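The edgeR fits, the fits within a number series, the list tests without each library, the covariate for acute injury under variable ventilation and the fits without the 2 shallowest control_chronic libraries were chosen after seeing the data. Every count of genes stayed within 1.5 times under a pseudocount of 10, without a filter and with edgeR, and with quantile normalization except over all arms, where 1 gene passed in place of 10. In fits limited to the groups compared, counts were 866 (chronic injury without ventilation), 2059 (variable ventilation, uninjured), 8 (acute injury, variable ventilation), 33 (modes after chronic injury) and 1 (modes over all arms), and 3886 for modes in uninjured lungs, which rose. For modes after acute injury limma then called 0 genes, with 4190 at an unadjusted p under 0.05 and 3632 by edgeR on all libraries. The main fit uses 1 spread per gene for all 8 groups, while these fits estimate it from fewer samples, those of the groups compared. Fewer samples alone do not account for the rise from 1538 to 3886 genes for modes in uninjured lungs. Whether groups differ in spread was not tested. Without control_chronic_113 and control_chronic_114 the counts were 701 for chronic injury and 1389 for constant ventilation after it, with fewer samples.

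With the number series as a covariate limma called 0 genes for modes in uninjured lungs (1582 at an unadjusted p under 0.05, and 504 higher and 947 lower by edgeR without series), 9 for modes after chronic injury (1560), 6 for the difference between these (1946) and 732 for acute injury under variable ventilation (3314). Within series 15 it called 151 genes for the last and 0 for modes in uninjured lungs (1770 at an unadjusted p under 0.05). Modes after acute injury gave 2006 genes with the series 15 libraries of acute_noisy and 5546 with those of series 14, and the cause was not tested.

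Leaving out 1 library gave 204 (without control_blank_016) to 3635 genes (without control_blank_074) for chronic injury without ventilation, and 2666 (control_blank_016) to 5419 (control_blank_074) for variable ventilation in uninjured lungs. For ventilation after chronic injury it gave 1181 (chronic_VCV_069) to 2065 (chronic_VCV_067) with constant and 2931 (chronic_noisy_084) to 5389 (control_chronic_117) with variable tidal volume, and 1555 (acute_noisy_047) to 6146 (acute_noisy_053) for acute injury under variable ventilation. Between modes it gave 1 (healthy_VCV_025) to 1982 (healthy_noisy_078) in uninjured, 780 (acute_VCV_040) to 4917 (acute_noisy_053) in acute and 8 (chronic_VCV_067) to 702 (chronic_VCV_069) in chronic lungs, and 1 (acute_VCV_040) to 52 (chronic_VCV_069) over all arms. The difference from uninjured lungs after chronic injury ran from 2535 (chronic_VCV_067) to 4765 (chronic_VCV_069) for modes and from 943 (control_blank_016) to 4933 (control_blank_074) for constant ventilation. Constant ventilation in uninjured lungs (6642 to 8658), acute injury under it (6851 to 7376) and the difference in mode effect after acute injury (4320 to 6757) stayed within 1.5 times. The report gives the count without each further library that moved one, except over all arms, where leaving out most of the libraries moved the count, and the cause was not tested beyond there being fewer samples.

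Of the list calls by camera, 74 held without each library in turn and the other 42 ended without at least 1, with fewer samples. Over leave-one-out fits of the T and NK cell list for modes after chronic injury, adjusted p ran from 0.000287 (without chronic_VCV_067) to 0.849 (without chronic_VCV_069), where the mean difference went from 0.39 to -0.01 and the direction reversed. For acute injury under variable ventilation the mean difference of the club cell list went from -0.51 to 0.32 without healthy_noisy_078 (adjusted p = 0.273), with the same camera direction. Mean differences of 29 called lists changed sign or moved by over 1.5 times without at least 1 library.

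Of the named gene values, 5 reversed. Quantile normalization put Sftpc at 0.206 (adjusted p = 0.425) for constant ventilation in uninjured lungs and 0.614 (adjusted p = 0.0455) after chronic injury. The series covariate put the difference in mode effect between chronic and uninjured lungs at 0.138 for Nkx2-1, -1.477 for Plunc and -0.916 for Scgb3a1, none past the threshold, and the cause was not tested. In edgeR 1279 named values kept direction and side of the threshold, 59 lost the call and 8 gained it, and after quantile normalization 1300 kept it and 42 lost it. The series covariate, where it could be fitted, left 103 and ended 215, and fits within series 15 left 42 and ended 138. Fits of only the groups compared left 1056, ended 276 and added 14, and leave-one-out fits left 10021, ended 1711 and added 27. The library of lowest depth was in control_chronic, with 6024093 reads.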

Other observations

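Tests against other splits of the libraries, in this part, were chosen after the counts were seen.

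By camera the glucocorticoid target list was called higher in each comparison of ventilated with unventilated lungs. Besides the 8 of 13 in healthy_VCV, a call that ended without control_blank_021 (camera adjusted p = 0.0865), 7 were higher in healthy_noisy (camera adjusted p = 0.000601), 4 in chronic_VCV (camera adjusted p = 0.000195) and 7 in chronic_noisy (camera adjusted p = 0.00223), or 7, 8 and 7 adjusted over the list alone. With an estimated correlation the adjusted p was 0.63, 0.339 and 0.612. Fkbp5, a co-chaperone of the glucocorticoid receptor, was higher by 1.89 ± 0.45, 2.31 ± 0.48, 1.48 ± 0.43 and 2.02 ± 0.43 in the 4 comparisons, and Mt2A, a metallothionein, by 2.95 ± 0.76, 3.77 ± 0.68 and 3.80 ± 0.68 in the last 3. In chronic_VCV, Fkbp5 lost its call without 3 of the 8 libraries, and was at 1.03 without chronic_VCV_069 (adjusted p = 0.173).

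B and plasma cell genes were called lower by camera in 3 of these comparisons, and not in healthy_VCV (camera adjusted p = 0.0914, 8 of 15 lower). The limits given above on shared libraries and number series apply here too. Beside healthy_noisy, they had 6 of 15 lower in chronic_VCV (10 adjusted over the list alone, camera adjusted p = 4.96e-06) and 5 in chronic_noisy (5 adjusted over the list alone, camera adjusted p = 0.0146), with adjusted p = 0.311 and adjusted p = 0.612 given an estimated correlation. Fcer2 was 7.59-fold, 8.4-fold and 4.33-fold lower in healthy_noisy, chronic_VCV and chronic_noisy, in this order, and 4.88-fold lower in healthy_VCV. Without chronic_VCV_069 the mean difference of the list in chronic_VCV went from -1.51 to -0.78 and Fcer2 was at -2.02, and without chronic_noisy_084 Fcer2 did not pass in chronic_noisy (adjusted p = 0.0641).

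Other splits of the same libraries into groups of the same sizes were counted for each comparison, the real one included. For 8 comparisons 1 split, the real one, reached the real count, which is the smallest share that these splits can give. The rule was set after the counts were seen and used on 14 comparisons without adjustment. Chance is thus made less likely but is not excluded. The splits take no account of the number series, so this says nothing on whether the series or the groups differ. The real count and the highest of the others were 2214 and 1523 for chronic injury without ventilation (56 splits), 8559 and 5690 for constant ventilation in uninjured lungs (35), 2205 and 7 for constant ventilation after chronic injury (56), and 5543 and 48 for variable ventilation after chronic injury (56). They were 7829 and 4826 for acute injury under constant ventilation (35), 1538 and 10 for modes in uninjured lungs (35), 5813 and 4149 for the difference in mode effect between acute and uninjured lungs (100), and 4435 and 2541 for that between chronic and uninjured lungs (100). The 4149 genes came from a split that puts all series 15 libraries on 1 side and all series 14 libraries on the other, and no fit with the series separates that comparison, since acute_VCV is series 12 alone. The 2541 genes also came from the split that parts series 15 from series 14, and with the series as a covariate the real comparison between chronic and uninjured lungs gave 6 genes. That split also keeps chronic_VCV apart from chronic_noisy, and healthy_noisy apart from healthy_VCV_025, healthy_VCV_057 and healthy_VCV_060. The split with 4149 genes likewise keeps healthy_noisy apart from these healthy_VCV libraries. Both counts therefore carry differences between real groups and are no separate evidence for a series effect. For modes in uninjured lungs the covariate left 0 genes by limma (1582 at an unadjusted p under 0.05, and 504 higher and 947 lower by edgeR without series), and leaving out healthy_VCV_025 left 1.

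In 4 comparisons other splits also reached the real count. For acute injury under variable ventilation 2 of 35 splits gave at least 3987 genes, the other 6314 when acute_noisy 053 of series 15 was grouped with the 3 healthy_noisy libraries, also of series 15. That split leaves both series 14 libraries on 1 side, and with the series as a covariate 732 genes passed. For modes after acute injury 2 of 35 splits gave at least 3609 genes, the other 4281 with acute_noisy 053 grouped with acute_VCV. Over all arms 5 of 100 splits gave at least 10 genes, the highest 2698, and the constant ventilation effect differed between chronic and uninjured lungs in at least 3564 genes in 8 of 100 splits, the highest 7151 in a split with all control_blank libraries (series 12) on 1 side and all healthy_VCV libraries (series 14 and 15) on the other. That split keeps the real control_blank and healthy_VCV groups apart, so its count carries the difference between them. The split with 2698 genes likewise keeps acute_noisy apart from acute_VCV. Splits of this kind still hold differences between real groups, so they cannot decide whether chance gives the real count. With 10 splits, too few for a share under 0.05, variable ventilation in uninjured lungs gave 4791 genes against 1 in the highest other split, and modes after chronic injury gave 362 against 1.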
